A study of Mus musculus with 6 samples.

How the data were processed

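Gene expression was measured in whole testis of 6 male C57BL/6J mice aged 10 weeks, 3 with a TAp73 knockout and 3 wild type, on 1-colour Agilent arrays with 1 array per mouse. TAp73 is the group of Trp73 transcripts that encode the transactivation domain of p73, a relative of the tumour suppressor p53. Per the labels' protocols, RNA was extracted with TRIzol and labelled with Cy3 by a low-input amplification kit. A separate label field names biotin as the label, and the scanner files hold 1 green channel.

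Per the file headers, the authors' scanner files were made with Feature Extraction 10.7.3.1 and a 1-colour gene expression protocol, on a design built on mouse genome build mm9. Their values are linear spot intensity, and the column used here is the background-subtracted processed signal that the authors deposited for each spot. The authors also deposited a series value table of probe intensity on a linear scale. Its columns have medians of 554.0 to 554.2 and 75th percentiles of 5000.5 to 5002.4, so the arrays had been brought to nearly the same distribution; how this was done is not given in the sources used here. Per the submitters' processing notes, limma was used, with no version given there.

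The labels of the 2 kinds of file oppose each other. Over probes, each array's deviations from the mean of the 6 arrays were correlated between the scanner files and the value table. Every scanner file labelled knockout matched a table column labelled wild type, and every one labelled wild type matched a column labelled knockout. The correlations with the matching columns were 0.83 to 0.99, the next best were 0.04 or lower, and those with the column of the same label were -0.33 to -0.20. The scanner files and the labels recorded with them were used throughout. Under the value table's own labels the groups change places, so that a rise becomes a fall. Scale and normalization of the table are known only from its values.

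Each array held 44397 spots, of which 1377 were control spots and 43020 were spots of 39429 probes. Control spots were left out. Spots that the scanner software had marked as non-uniform or as population outliers, 163 to 280 per array, were set to missing, and saturated spots were kept. Log2 processed signals were averaged over the spots of a probe and each array's 75th percentile was subtracted. A probe was tested if it was well above background on at least 3 of the 6 arrays, whatever their group, and had at least 2 values in each group. This left 31801 probes. The array's own accession, without its version, was matched to RefSeq transcripts of assembly GRCm38.p6, which was used for names and for the order of genes along the chromosome, never for coordinates. Of the 39429 probes, 26055 were named by 1 of 19751 gene symbols, none matched several genes, and 13374 stayed unnamed here. Of the tested probes 22273 had a symbol, for 17041 genes.

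Differences between the groups, knockout minus wild type, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term). Benjamini-Hochberg adjustment ran over all tested probes, with an adjusted p under 0.05 as the threshold. Adjusted p-values of single probes given below are from this fit unless another setting is named beside them. A probe that was not well above background on any array of a group gives only a bound. Its fold is then written as at least the brighter group's mean over the dimmer group's mean, after each array of the dimmer group was raised to the lowest signal well above background on that array. Levels of different probes were not compared.

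Before the data were examined, 26 gene lists were fixed: adhesion receptors, junction proteins, protease inhibitors, extracellular proteases, spermatogonia, spermatocytes, round spermatids, elongating spermatids, Sertoli cells, Leydig cells and steroid synthesis, cholesterol synthesis, peritubular myoid cells, macrophages and immune cells, endothelial cells, epididymis and efferent ducts, blood cells, immediate early and heat shock genes, circadian clock, extracellular matrix, axoneme and intraflagellar transport, ciliogenesis regulators, p53 family targets, apoptosis machinery, interferon response, phagocytosis and lysosome, and retinoid metabolism and signalling. Each gene was represented by its brightest complete probe, giving 16947 measured genes. Lists were tested against all other measured genes with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 26 lists. Camera with an estimated correlation and fry were alternatives; fry asks only whether the genes of a list move one way on balance. The design, the tests, the alternatives and the rule for naming genes were fixed at the same time. The rule takes, among called probes whose groups do not overlap, the 14 largest rises and the 14 largest falls, 1 probe per gene, up to 4 called members of each list, or 2 with the smallest p where no member was called, and Trp73. A result that this rule gives is not reported here. Genes that fall outside it are said to be chosen after their values were seen.

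The alternatives were normexp background correction with an offset of 50, quantile normalization, both together, scaling to the median, no filter on dim probes, a filter requiring all 6 arrays, slide as a block, slide 1 alone, the replicate number as a block, a trended and robust variance model, array weights, marked spots kept, the authors' value table with its columns matched to the arrays, each array left out in turn, and other thresholds. Normexp had been planned on the mean foreground signal; it was run on the median foreground and background signals of all spots, since the files hold no mean foreground. After the data were seen, the value table under its own labels, lists without saturated probes and the minimum of 2 values per group were added.

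The arrays came from 2 slides. Slide 1 held knockout replicates 1 and 2 and wild type replicates 1 and 3, and slide 2 held knockout replicate 3 and wild type replicate 2. The code was tested on simulated arrays with the measured means and spread of 31618 probes, of which 67 were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. It called 17.9%, 71.6% and 80.3% of them, and 7 of its 120 calls were of unchanged probes. A simulated shift of 0.3 in 1 list was called, and 0 of the other 25 lists were called at the adjusted threshold. The simulated noise was independent between probes, while the correlation estimated for the measured lists reached 0.642 (elongating spermatids). The simulation therefore does not show how often a list of correlated genes is called without a shift. Nor does it show how many single probes are called falsely where probes move together across arrays. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The number of arrays, 3 per group, limits the precision of every value.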

Results

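The arrays of 3 TAp73 knockout and 3 wild type testes were compared to ask which transcripts differ where TAp73 is missing, with cell adhesion and sperm maturation as the study's stated subject. Each array read 39429 probes, of which 74.4% to 84.4% were well above background and 1.6% to 4.4% were saturated. Correlations between arrays of the same group were 0.987 to 0.996 over probes. Those between groups overlapped this range. Knockout replicates 2 and 3 reached 0.9922 and 0.9931 with a wild type array, above their 0.9872 and 0.9885 with knockout replicate 1. Knockout replicate 1 stood apart from the others on the first principal component, at -66.2 against -4.9 to 30.8, a component that held 39.8% of the variance.

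The targeted gene was lower in every array labelled knockout. Of its 3 tested probes, A_52_P193555 read 605, 548 and 587 units of processed signal in wild type replicates 1 to 3 and 17.2, 4.81 and 5.17 in the knockouts, where it was well above background on 1 of 3 arrays. Its log2 difference was -6.01 (SE 0.41, adjusted p = 0.00369). Trp73 probe A_55_P1988133 differed by -3.21 (adjusted p = 0.00213) and was well above background on 2 of 3 knockout arrays. Trp73 probe A_52_P410636 differed by -0.99 (adjusted p = 0.0104) and stayed well above background on all 3. With slide as a block, A_52_P193555 kept its difference of -6.01 (adjusted p = 0.0183); within slide 1 it was -5.77 (adjusted p = 0.183) and within the slide 2 pair -6.48. Where these probes lie relative to the deleted exons is not given in the sources used here. The authors' value table carries the opposite labels for the same arrays, and under those Trp73 would be 6.01 higher in the knockout; all directions below follow the scanner files.

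**Figure D1:**
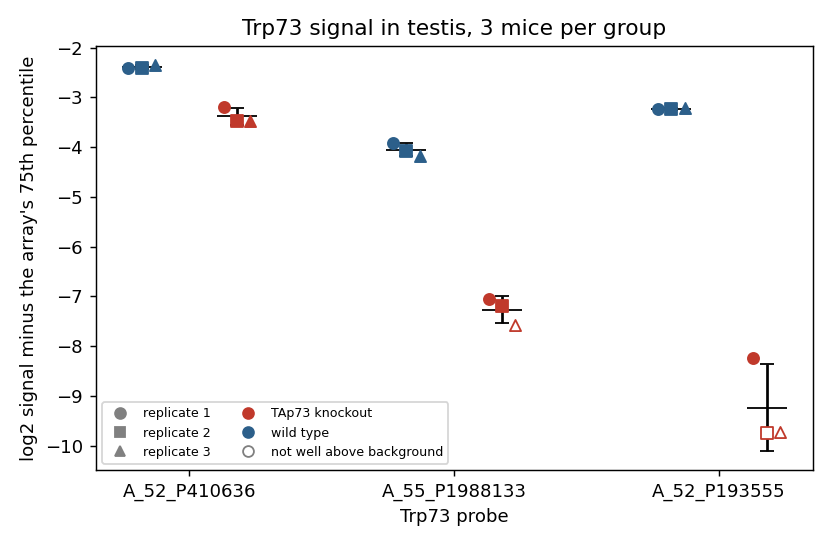
Trp73 signal on each array for 3 probes, as log2 signal minus the array's 75th percentile (points: single mice, open where not well above background; bars: mean and SD of 3 mice). For each probe the 3 knockout mice lie below the 3 wild type mice, with means of -9.23 against -3.23 for A_52_P193555.

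Timp1, a secreted inhibitor of metalloproteinases, was 14.5-fold lower in the knockout (log2 difference -3.86, SE 0.13, adjusted p = 0.000863). Serpina3n, a serine protease inhibitor, was 8.36-fold lower (-3.06, adjusted p = 0.00278), and Mpzl2, an adhesion protein of epithelia, was 10.6-fold lower (-3.40, adjusted p = 0.0042). The water channel Aqp5 was 14.1-fold lower (-3.82, adjusted p = 0.0437), with signals of 57.9 in knockout replicate 1 and 280 and 249 in replicates 2 and 3; without replicate 1 the difference was -3.00 (adjusted p = 0.00519). The secreted signalling protein Wnt4 was 9.17-fold lower (-3.20, adjusted p = 0.00229; well above background on 1 of 3 knockout arrays), with -0.39 under normexp (adjusted p = 0.71), and the insulin-like growth factor binding protein Igfbp3 6.85-fold lower (-2.78, adjusted p = 0.00457). Gpnmb, a glycoprotein of phagocytic cells, was not well above background in any knockout and was at least 7.69-fold lower (adjusted p = 0.0455). The other named falls were Cd83, Lrg1, Wfdc18, 4930486L24Rik, the endothelial guidance receptor Robo4 and the chemokine Ccl9, with log2 differences of -3.23 to -2.71.

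Called rises were fewer and mostly smaller. Tas1r1, a subunit of the umami taste receptor, was 47.3-fold higher (log2 difference 5.57, SE 0.37, adjusted p = 0.00369). Dab1, an adaptor of reelin signalling, was higher by 2.83 (adjusted p = 0.0314), although it was well above background on 1 of 3 wild type arrays. The T-box transcription factor Eomes rose by 1.55 (adjusted p = 0.0152), the transcription factor Myb by 1.22 (adjusted p = 0.0492), and the claudin Cldn10 by 1.06 (adjusted p = 0.0455). Eomes, Myb and Pla2g12b were well above background on 2 of 3 wild type arrays. Cacna1f, at least 1.22-fold higher, and Lrrtm3, at least 1.07-fold higher, were not well above background in any wild type. Their log2 differences were as low as 0.155 and 0.165 under other processing. Slc22a29, Pla2g12b and Adra1d rose by 0.61 to 0.89. The remaining 5 of the 14 largest rises, Tas1r1 included, lay among the 50 tested genes on either side of Trp73 on its chromosome. They were Tas1r1, Ttc34 (1.19), Zbtb48 (0.93), Morn1 (0.75) and Klhl21 (0.61).

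**Figure D2:**
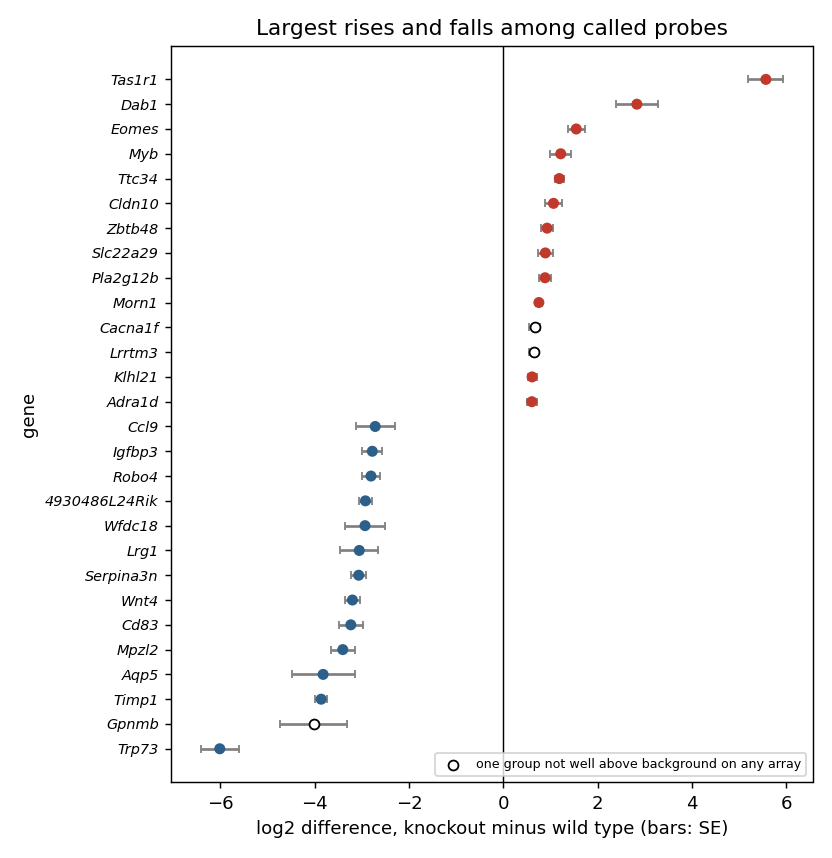
Log2 difference, knockout minus wild type, with its SE (n = 3 per group), for the 14 largest rises and the 14 largest falls among called probes whose groups do not overlap. Open points mark genes not well above background on any array of 1 group; Trp73 lies at -6.01 and Tas1r1 at 5.57, and the falls reach further than the other rises.

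In all, 838 probes were lower in the knockout and 79 were higher, so that 91.4% of the calls were lower. Of the lower probes 721 had a symbol, for 648 genes, and of the higher probes 43, for 41 genes. The other called probes were unnamed. Of all called probes, 162 were at least 2-fold lower and 10 at least 2-fold higher. At an unadjusted p under 0.05 the balance differed, with 3464 probes lower and 3897 higher. The groups did not overlap for 31.7% of tested probes, where chance gives 10% for a single probe. All probes share the same 6 arrays and can move together, so this contrast is not a test of genotype. The median within-group SD was 0.12 and the median difference over all tested probes was 0.06. Among 188 called genes with several tested probes, all probes had the same sign in 157. Quantile normalization gave 868 lower and 217 higher (80.0% lower) and median scaling 569 and 143 (79.9% lower; 2659 lower and 7470 higher at an unadjusted p under 0.05). With slide as a block the counts were 299 and 15, and within slide 1 they were 0 and 0 (limma; 1809 lower and 1332 higher at an unadjusted p under 0.05). Normexp background correction alone left 0 and 0 calls (limma; 810 lower and 1075 higher at an unadjusted p under 0.05), and normexp with quantile normalization 405 and 91. Lower and higher calls were 418 and 28 without knockout replicate 1, 116 and 8 without replicate 2, 145 and 7 without replicate 3, 420 and 14 without wild type replicate 1, 117 and 12 without replicate 2, and 229 and 19 without replicate 3.

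Adhesion receptors were lower in the knockout. Of 51 measured members, 8 fell, 0 rose and 43 did not pass the test; adjusted over the list alone, 19 fell and 3 rose. The integrin alpha chains Itga5 (-1.28, adjusted p = 0.00384; -0.08 under normexp, adjusted p = 0.926) and Itga9 (-0.99, adjusted p = 0.0111) fell, as did the collagen receptor Ddr1 (-1.43, adjusted p = 0.00369). The largest fall was that of Itgax (-1.93, adjusted p = 0.00369), an integrin of dendritic cells and macrophages, and the list of macrophages and immune cells was lower in the same arrays, with a median of -0.39. The median over adhesion receptors was -0.18 (camera adjusted p = 3.36e-06; adjusted p = 0.135 with an estimated correlation), -0.21 within slide 1 and -0.27 in the slide 2 pair. Under normexp this median was 0.05, where the median of all tested probes had moved to 0.22.

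Junction proteins showed no shift as a list. Of 76 measured members, 1 rose, 2 fell and 73 did not pass; adjusted over the list alone, 2 rose and 2 fell. Cldn10 rose, while cingulin, Cgn (-0.58, adjusted p = 0.0328), and the junctional adhesion molecule F11r (-0.45, adjusted p = 0.04) fell; both are components of tight junctions. The median was -0.04 (camera adjusted p = 0.789). It lay above 0 at 0.34 under normexp, 0.02 under quantile normalization, 0.02 with median scaling and 0.04 within slide 1. Under normexp all tested probes had a median of 0.22.

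Among protease inhibitors 11 of 96 measured members fell and 0 rose, with 85 not past the threshold; adjusted over the list alone, 22 fell and 0 rose. In limma 6 were higher at an unadjusted p under 0.05. Beside Timp1 and Serpina3n the falls included the whey acidic protein family members Wfdc18 (7.62-fold lower, adjusted p = 0.0255; well above background on 2 of 3 knockout arrays) and Wfdc17 (3.35-fold lower, adjusted p = 0.0071). The test called the list lower (camera adjusted p = 0.00727; adjusted p = 0.377 with an estimated correlation). The mean was -0.24 but the median was 0.02, so the call rests on a minority of members. Without genes saturated on any array, a setting added after the data were seen, the median was -0.061 (camera adjusted p = 0.00316). Without wild type replicate 3 the call was lost (adjusted p = 0.0535), as it was under normexp (adjusted p = 0.0647). Within slide 1 the median was -0.01 and in the slide 2 pair -0.12. In the same arrays the lists of macrophages and immune cells (median -0.39), Sertoli cells (-0.31) and blood cells (-0.61) were lower.

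Extracellular proteases were not called as a list (camera adjusted p = 0.285; median 0.00, mean -0.07, test direction lower). Of 139 measured members, 11 fell, 1 rose and 127 did not pass; adjusted over the list alone, 19 fell and 3 rose. Falls were measured for Adam23 (-1.30, adjusted p = 0.00369), an ADAM family protein, the metalloproteinase Mmp23 (-1.11, adjusted p = 0.0273), the serine protease homologue Prss35 (-0.999, adjusted p = 0.0188) and the lysosomal protease cathepsin S, Ctss (-0.87, adjusted p = 0.0148). Mmp23 is 25 tested genes away from Trp73.

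Markers of germ cells were tested in 4 lists by stage. Among spermatogonia 1 of 22 measured members rose, Eomes, 0 fell and 21 did not pass, with the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.461). Limma gave 2 lower spermatogonial genes at an unadjusted p under 0.05. The list of 38 spermatocyte genes was higher (median 0.21, camera adjusted p = 5.27e-05; adjusted p = 0.138 with an estimated correlation), with 0 members called, also over the list alone, and 8 higher and 0 lower at an unadjusted p under 0.05 in limma. Its smallest p-values were those of Brdt, a bromodomain protein of meiotic and later germ cells (0.39, adjusted p = 0.121), and of Spo11, which makes the breaks of meiotic recombination (0.24, adjusted p = 0.146). Within slide 1 and in the slide 2 pair the median was 0.21, and quantile normalization lowered it to 0.08 (adjusted p = 0.0107).

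The 27 round spermatid genes had a median of 0.23 (camera adjusted p = 0.000111; adjusted p = 0.308 with an estimated correlation) and the 36 elongating spermatid genes 0.26 (camera adjusted p = 1.32e-06; adjusted p = 0.377 with an estimated correlation). In both lists 0 members were called, over all probes or over the list alone; at an unadjusted p under 0.05 limma gave 9 and 11 higher and 0 lower. The smallest p-values were those of Zpbp (0.25, adjusted p = 0.106) and Agfg1 (0.26, adjusted p = 0.111), both needed for the acrosome, and of Spata19 (0.34, adjusted p = 0.0552) and the testis kinase Tssk2 (0.20, adjusted p = 0.159). The probe was saturated on at least 1 array for 33 of the 36 elongating, 12 of the 27 round spermatid and 12 of the 38 spermatocyte genes, and on all 6 arrays for 5, 0 and 1. The 75th percentile used for scaling was 0.26 higher in wild type on the log2 scale, so a spot at the scanner's limit on all arrays appears 0.26 higher in the knockout. Under quantile normalization the medians were 0.03 (round, adjusted p = 0.245) and 0.02 (elongating, adjusted p = 0.483). Within slide 1 they were 0.24 and 0.25, and in the slide 2 pair 0.22 and 0.26.

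Markers of Sertoli cells, the somatic nurse cells of the seminiferous tubule, were lower. Of 32 measured members 4 fell, 0 rose and 28 did not pass; adjusted over the list alone, 12 fell and 0 rose. They were the transcription factors Sox9 (-0.64, adjusted p = 0.0186) and Gata1 (-0.51, adjusted p = 0.0464), the intermediate filament protein vimentin, Vim (-0.58, adjusted p = 0.028), and Aard (-0.44, adjusted p = 0.0401). For 7 of the 32 the probe was saturated on at least 1 array. Those 7 had a median of 0.27, near the scaling difference of 0.26, and the other 25 had a median of -0.39. Limma gave 4 higher Sertoli genes at an unadjusted p under 0.05. The median was -0.31 (camera adjusted p = 0.000111; adjusted p = 0.135 with an estimated correlation), -0.27 within slide 1 and -0.29 in the slide 2 pair.

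Markers of macrophages and other leukocytes were lower too. Of 26 measured members 6 fell, 0 rose and 20 did not pass; adjusted over the list alone, 14 fell and 0 rose, and 0 were higher at an unadjusted p under 0.05 in limma. Cd74, the invariant chain of antigen presentation, fell (-1.12, adjusted p = 0.0124), as did the complement subunit C1qc (-0.72, adjusted p = 0.0198), Ctss and lysozyme, Lyz1 (-0.96, adjusted p = 0.021), a gene with the close paralog Lyz2. The median was -0.39 (camera adjusted p = 1.32e-06; adjusted p = 0.135 with an estimated correlation), -0.28 within slide 1 and -0.53 in the slide 2 pair. The list of blood cells had a median of -0.61 in the same arrays, with 0 of 7 members called (limma; 4 lower and 0 higher at an unadjusted p under 0.05) and leave-one-out medians of -0.82 to -0.38 (camera adjusted p = 0.00526; adjusted p = 0.309 with an estimated correlation and 0.0566 with fry).

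Genes of phagocytosis and the lysosome, which Sertoli cells and macrophages share, were lower. Of 26 measured members 7 fell, 0 rose and 19 did not pass; adjusted over the list alone, 13 fell and 0 rose, and 1 was higher at an unadjusted p under 0.05 in limma. Beside Gpnmb they included the engulfment receptor Mertk (-0.74, adjusted p = 0.0265), its ligand Pros1 (-0.59, adjusted p = 0.0152) and the lysosomal prosaposin, Psap (-0.69, adjusted p = 0.0279). The median was -0.34 (camera adjusted p = 1.32e-06; adjusted p = 0.191 with an estimated correlation), -0.33 within slide 1 and -0.38 in the slide 2 pair. Of 28 interferon response genes 1 fell, the immunoproteasome subunit Psmb8 (-0.56, adjusted p = 0.0414), 0 rose and 27 did not pass, with 10 lower and 0 higher adjusted over the list alone. Limma gave 0 higher interferon genes at an unadjusted p under 0.05. Their median was -0.28 (camera adjusted p = 3.68e-05, and adjusted p = 0.241 with an estimated correlation), -0.22 within slide 1 and -0.39 in the slide 2 pair. Under normexp it was 0.16, against 0.22 over all tested probes, and the call was lost (camera adjusted p = 0.127).

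The other somatic cell lists were not called. For Leydig cells, the androgen-producing cells, 3 of 29 measured members fell and 0 rose (median -0.10, camera adjusted p = 0.13); adjusted over the list alone, 8 fell and 1 rose. The falls were in the steroid enzymes Hsd11b1 (-0.85, adjusted p = 0.032) and Hsd3b1 (-0.76, adjusted p = 0.0369) and in Tspo, a mitochondrial outer membrane protein (-0.54, adjusted p = 0.0414). Among 14 peritubular myoid genes 1 fell, the smooth muscle protein Smtn (-0.56, adjusted p = 0.0293), and 0 rose (median -0.10, camera adjusted p = 0.496). Among 18 endothelial genes 2 fell, Robo4 (6.98-fold lower, adjusted p = 0.00369) and Ly6c1 (-0.67, adjusted p = 0.0248), and 0 rose (median -0.08, camera adjusted p = 0.0979). Adjusted over the list alone, the myoid and endothelial counts were unchanged, at 1 and 2 lower. At an unadjusted p under 0.05, limma gave 2 higher Leydig, 2 higher myoid and 1 higher endothelial genes. Under normexp the 3 medians were 0.01, 0.13 and 0.13, against 0.22 over all tested probes. The Leydig list was called lower by the test there (camera adjusted p = 0.00733). The endothelial list was called without wild type replicate 3 (median -0.14, adjusted p = 0.0179) and over all tested probes of a gene (median -0.14, adjusted p = 0.0391).

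Extracellular matrix genes were lower as a list, with 5 of 70 measured members falling, 0 rising and 65 not past the threshold; adjusted over the list alone, 11 fell and 0 rose. In the same arrays the medians of macrophages and immune cells (-0.39), Sertoli cells (-0.31) and blood cells (-0.61) lay below 0. Matrix Gla protein, Mgp (-0.997, adjusted p = 0.00369), the basement membrane laminin chain Lamb2 (-0.83, adjusted p = 0.0142) and the proteoglycans decorin, Dcn (-0.70, adjusted p = 0.028), and biglycan, Bgn (-0.69, adjusted p = 0.022), fell. Limma gave 3 higher matrix genes at an unadjusted p under 0.05. The median was -0.12 (camera adjusted p = 0.00602; adjusted p = 0.408 with an estimated correlation), -0.05 within slide 1, -0.19 in the slide 2 pair and 0.10 under normexp. With 1 array left out it ran from -0.22 without wild type replicate 1 to -0.015 without wild type replicate 3. Fry did not call the list (adjusted p = 0.119). Under normexp all tested probes had a median of 0.22.

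The list of p53 family targets was lower. It holds genes that p53 family proteins are known to activate, and also the family members Trp53 and Trp63. In the same arrays the lists of macrophages and immune cells (median -0.39), phagocytosis (-0.34) and Sertoli cells (-0.31) were lower. Of 29 measured members 4 fell, 0 rose and 25 did not pass; adjusted over the list alone, 5 fell and 0 rose. The 4 called falls were the death receptor Fas (-1.42, adjusted p = 0.0104), Phlda3 (-1.28, adjusted p = 0.0104), Sfn (-0.47, adjusted p = 0.0294; 0.05 under normexp) and Ddit4 (-0.46, adjusted p = 0.0391). Among p53 targets 2 were higher at an unadjusted p under 0.05 in limma. The median was -0.16 (camera adjusted p = 0.00404; adjusted p = 0.234 with an estimated correlation), -0.13 within slide 1, -0.14 in the slide 2 pair and -0.24 (without wild type replicate 1) to -0.07 (without knockout replicate 1) with 1 array left out. Of 31 genes of the apoptosis machinery 6 fell, among them the initiator caspase Casp8 (-0.84, adjusted p = 0.012), the BCL2 family members Bik (-0.81, adjusted p = 0.0278) and Bok (-0.70, adjusted p = 0.039) and the inhibitor of apoptosis Birc3 (-0.72, adjusted p = 0.0152). None rose and 25 did not pass; adjusted over the list alone, 11 fell and 2 rose, and 2 were higher at an unadjusted p under 0.05 in limma. Their median was -0.17 (camera adjusted p = 0.00277; adjusted p = 0.191 with an estimated correlation), -0.10 within slide 1, -0.29 in the slide 2 pair and -0.24 (without knockout replicate 1) to -0.11 (without knockout replicate 3) with 1 array left out.

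With slide as a block, every list called here stayed called. With the correlation estimated for each list, none was called.

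**Figure D3:**
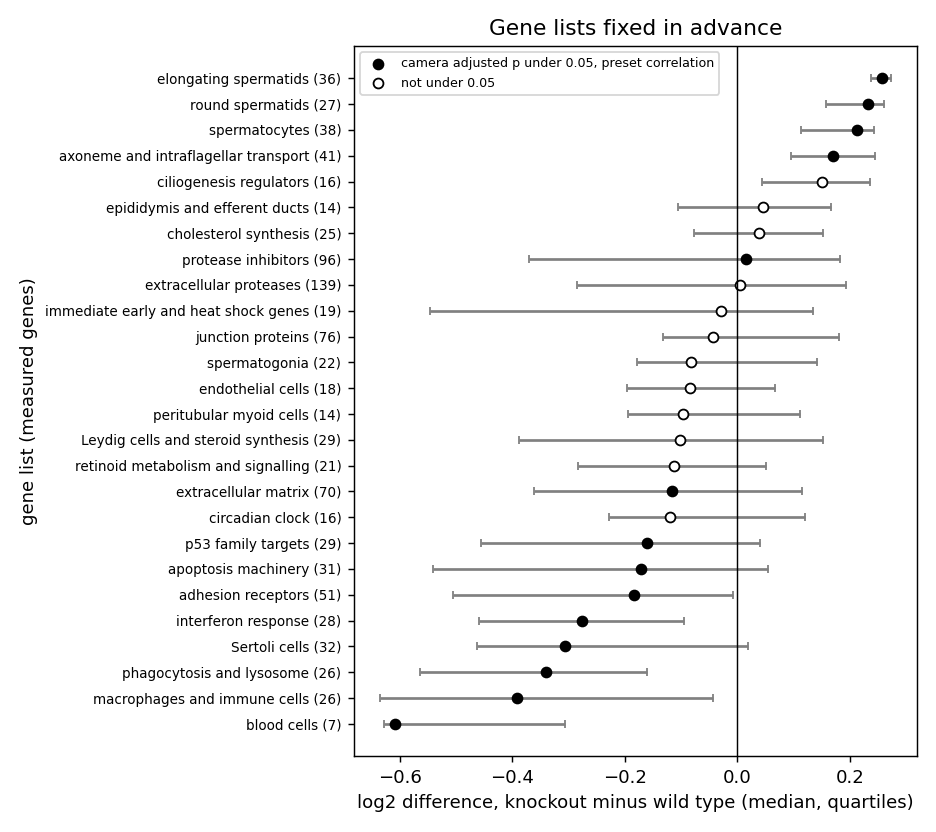
Median log2 difference, knockout minus wild type, over the measured genes of each of the 26 lists (number of genes in brackets), with bars from the lower to the upper quartile of the genes and filled points where camera called the list. Medians run from -0.61 for blood cells to 0.26 for elongating spermatids, and the protease inhibitors are called lower with a median of 0.02.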

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

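The tests of the exchanged labels and of the genes next to Trp73 were chosen after the results were seen. The tests of the germ cell lists and the splits of the arrays are recorded as written before. The germ cell tests name their lists as higher, however, which presupposes the result of the list test. They were thus fixed before their own outcome at most.

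The authors' value table, which no comparison of the report uses as its main values, drew attention because its Trp73 signal is higher in the columns labelled knockout. The difference there was 6.01 (SE 0.35) for probe A_52_P193555, 3.18 for A_55_P1988133 and 0.94 for A_52_P410636. Under the scanner files' labels the difference was -6.01 (SE 0.41), from the same arrays. These are the values that raised the question, so they are not a separate test. Had the scanner files been exchanged, each of these probes would be higher in the knockout. A_52_P193555 would then be well above background on only 1 of 3 wild type arrays. The Trp73 values thus argue against exchanged scanner files, and exchanged table columns would give them. This reading, like the use of the scanner files' labels, assumes that the deletion could only lower the signal of these probes. Their position in the gene was not known here.

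Of the 100 tested genes nearest to Trp73, 50 on each side, 8 were called, or 8.0%, against 4.0% of the other 16940 tested genes. Strain variants in a chromosome segment carried along with the targeted allele could produce such a cluster, but at this window Fisher's exact test gave p = 0.0652 (odds ratio 2.08, 95% interval 0.87 to 4.29), so they cannot be told apart from chance. By Fisher's exact test the 25 nearest on each side gave p = 0.0149 and a window of 100 before and the 55 tested genes after Trp73 that remain on the chromosome p = 0.299, and for rises alone, counted because those names had been seen, 5 of 41 lay within 50 (Fisher's exact test, p = 3.99e-06). Probes that lost their match to such variants can only dim, so by construction this cannot apply to the 5 called genes there that rose with no overlap between the groups, while for the 3 that fell, Mmp23 (-1.11), Vwa1 (-0.60) and H6pd (-0.50), it stays open; Vwa1 and H6pd were chosen after their values were seen. An effect of the altered locus on its neighbours, or of TAp73 itself, stays open and was not tested.

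The higher lists of meiotic and haploid germ cells may reflect the brightness of their probes. Over members saturated on no array the median was 0.17 for 26 spermatocyte genes (95% interval 0.10 to 0.21) and 0.17 for 15 round spermatid genes (0.13 to 0.24). Both lay above the 0.05 of all measured genes, so in these 6 arrays the rise was not limited to saturated members. The intervals treat genes as independent, although the estimated correlations were 0.033 and 0.193. They describe the spread between genes and not between mice, so they cannot decide the cause. For elongating spermatids only 3 such genes remained, with a median of 0.34. Among 10000 random lists matched on mean signal, the spermatocyte median lay at percentile 99.3, above their central 95% of 0.09 to 0.20. The rule written beforehand counts this against a trend with brightness as the whole of it. The percentile does not decide it, since genes of the random lists were drawn singly, without the list's estimated correlation of 0.033. In addition, 12 of the 38 members were saturated on at least 1 array. The round spermatid median lay at percentile 87.4, inside 0.16 to 0.25, as a difference that grows with brightness predicts. The elongating spermatid median lay at percentile 99.1, which the rule written beforehand counts against brightness. That verdict was set aside once seen, since 33 of 36 members were saturated on at least 1 array (5 on all 6). The matched lists, at 0.23 to 0.26, also lie close to the scaling difference of 0.26. Those 33 members had a median of 0.257, where scaling alone gives 0.258 to a spot at the scanner's limit on all arrays. With 1 array left out, which also changes the scaling, the list's median ran from 0.197 to 0.358. Under quantile normalization it was 0.016 (camera adjusted p = 0.483). The rise of this list therefore cannot be told apart from the scaling. A different share of germ cells stays open because matched genes could be germ cell genes themselves.

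Splitting the 6 arrays into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 79 higher and 838 lower probes, the highest count in 1 direction of any other split was 1, and 1 of the 10 splits, the real one, gave as many.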

How the results depend on the processing

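The value table under its own labels and the lists without saturated probes were run after the data were seen; the cause of a change was not tested unless stated. Higher and lower counts were 0 and 0 under normexp, 217 and 868 under quantile normalization, 143 and 569 with median scaling, 91 and 405 with normexp and quantile normalization, 13 and 349 without a filter (more probes tested), 165 and 1109 with all 6 arrays above background, 15 and 299 with slide as a block, 0 and 0 within slide 1 (fewer arrays), 326 and 1275 with trended robust variances, 339 and 1486 with array weights, 216 and 876 with the value table matched to the arrays and 876 and 216 under its own labels, 577 and 1688 at an adjusted p under 0.10, and 10 and 162 with at least 1 on the log2 scale. Keeping marked spots moved neither count by over 1.5 times. Leaving out 1 array, which leaves fewer arrays, gave 7 to 28 higher and 116 to 420 lower; 121 of the 917 calls were kept without knockout replicate 2 and 394 without knockout replicate 1. Quantile normalization kept 829 of the 917.

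Whether the replicate numbers pair the mice is not known, and no sample is tied to its own number. Same-numbered arrays had correlations of -0.03, -0.08 and -0.09. Knockout and wild type arrays that shared a slide also had only -0.025 to 0.095, so such values cannot exclude pairing. With the replicate number as a block, 1 probe was higher and 9 lower, and Trp73, at -6.01, had an adjusted p of 0.0686.

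Under the scanner files' labels Trp73 probe A_52_P193555 stayed lower in the settings that tested it, which the filter on all 6 arrays does not, and lost its call under normexp (-1.88, adjusted p = 0.537) and within slide 1 (-5.77, adjusted p = 0.183). Trp73 probe A_52_P410636 lost its call in 6 settings, among them without knockout replicate 2 (-0.94), knockout replicate 3 (-0.95) or wild type replicate 2 (-1.01). With an estimated correlation the medians stay and no call holds: adhesion receptors -0.18, protease inhibitors 0.015, spermatocytes 0.21, round spermatids 0.23 and elongating spermatids 0.26; fry also lost the last (0.26, adjusted p = 0.0751). Protease inhibitors were lost under normexp (0.22), with leave-one-out medians of -0.061 to 0.044. Round and elongating spermatids were lost under quantile normalization (0.031 and 0.016), normexp with quantile normalization (0.038 and 0.00) and the matched value table (0.031 and 0.016).

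Under the value table's own labels Trp73 was 6.01, adhesion receptors 0.21, protease inhibitors 0.018, spermatogonia 0.064 and spermatocytes -0.078. Round spermatids were -0.031 and elongating spermatids -0.016 there. Exchanging the labels turns each of the table's differences by construction. The protease inhibitor median was -0.018 in the matched table and 0.018 under the table's own labels. In the main values it was 0.015, so against these its sign stayed while the test's direction turned. Medians of uncalled lists near 0 changed sign. Junction proteins were 0.34 under normexp, 0.021 under quantile normalization, 0.018 with median scaling, 0.012 with normexp and quantile normalization, 0.038 within slide 1, 0.015 in the matched table and -0.028 to 0.009 with 1 array left out, the last without knockout replicate 3. Extracellular proteases were -0.034 unfiltered, -0.015 with array weights, 0.00 with marked spots kept, -0.001 in the matched table, -0.017 without saturated probes, -0.006 over all probes of a gene and -0.004 to 0.062 with 1 array left out. Normexp moved the median of all tested probes to 0.22, so values above 0 there need not lie above the other probes. Under normexp spermatogonia were 0.026, myoid cells 0.13, endothelial cells 0.13, immediate early genes 0.20, clock genes 0.16, Atf3 0.24, Egr2 0.003 and Sfn 0.051. Beside Trp73, named falls that kept their sign but shrank under normexp included Itga5 (-0.08), Bgn (-0.12), Birc3 (-0.18), Psmb8 (-0.21), Hsd11b1 (-0.23), Wnt4 (-0.39), Gpnmb (-0.65), Ccl9 (-0.69) and Wfdc18 (-0.95), and no named gene passed there. Dim rises shrank too. Over all alternatives other than leaving out 1 array, the lowest values were 0.155 for Cacna1f, 0.165 for Lrrtm3, 0.189 for Pla2g12b, 0.399 for Myb and 1.00 for Dab1. Brighter rises held, with lowest values of 4.59 for Tas1r1, 0.98 for Ttc34 and 0.70 for Morn1. The weakest falls there were -1.52 for Serpina3n and -1.50 for Igfbp3. With 1 array left out Aqp5 ran from -4.29 to -3.00 and Gpnmb from -4.71 to -3.33. Others that turned were Leydig cells without wild type replicate 2 (0.048), cholesterol synthesis with array weights (-0.017) and with 1 array left out (-0.014 to 0.119), myoid cells within slide 1 (0.00) and immediate early genes above background on all 6 arrays (0.005). Of the other comparisons of single genes and lists with an alternative, 1353 kept direction and side of the threshold, 627 lost the call, 25 gained one and 12 turned.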

Other observations

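Further lists described neither adhesion nor the cell types of the tubule wall, and are given as values. Of 41 measured genes of the axoneme and intraflagellar transport, which build the sperm tail, 0 were called, also adjusted over the list alone, with 11 higher and 0 lower at an unadjusted p under 0.05 in limma. Dnah5, an axonemal dynein heavy chain, had a log2 difference of 0.73 (adjusted p = 0.055; well above background on 2 of 3 wild type arrays) and Ift172 of 0.30 (adjusted p = 0.0931). The median was 0.17 (camera adjusted p = 0.00026; adjusted p = 0.135 with an estimated correlation) and 0.03 under quantile normalization, where the call was lost (adjusted p = 0.279). It lay at percentile 73.3 of random lists matched on mean signal, inside their central 95% of 0.10 to 0.20, and 9 of the 41 probes were saturated on at least 1 array. Among 16 ciliogenesis regulators 1 rose, Myb, and 0 fell, with 2 higher adjusted over the list alone (median 0.15, camera adjusted p = 0.0525); 8 alternatives called the list, among them quantile normalization (adjusted p = 0.0351), slide as a block (adjusted p = 0.0399) and fry (adjusted p = 0.00533), and with an estimated correlation it was not called (adjusted p = 0.234). Limma gave 0 lower ciliogenesis regulators at an unadjusted p under 0.05.

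Of 7 measured blood cell genes 0 were called, and 1 was lower adjusted over the list alone; 4 were lower and 0 higher at an unadjusted p under 0.05 in limma. The platelet chemokine Pf4 differed by -0.41 (adjusted p = 0.0834) and the haemoglobin gene Hbb-bt by -0.65 (adjusted p = 0.182), whose paralogs share sequence. The median was -0.61 (camera adjusted p = 0.00526; adjusted p = 0.309 with an estimated correlation; adjusted p = 0.0566 with fry) and ran from -0.82 without knockout replicate 1 to -0.38 without knockout replicate 3. Of 14 epididymal genes 0 were called, over all probes, the list alone or an unadjusted p under 0.05 in limma (median 0.05, camera adjusted p = 0.753). Defb21 differed by 0.19 (adjusted p = 0.241), and Cst8, whose probe was saturated on 3 knockout and 2 wild type arrays, by 0.23 (adjusted p = 0.255).

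Of 19 immediate early and heat shock genes 2 fell and 0 rose. The falls were Atf3 (at least 4.21-fold lower, adjusted p = 0.0123) and Egr2 (-1.54, adjusted p = 0.0401), both transcription factors induced by stimulation. Under normexp they lay at 0.24 and 0.003, where all tested probes had a median of 0.22. Adjusted over the list alone, 5 fell and 1 rose (median -0.03, mean -0.35, camera adjusted p = 0.0831; called with median scaling, adjusted p = 0.0462, without knockout replicate 1, adjusted p = 0.049, and without wild type replicate 1, adjusted p = 0.0243), with 2 higher at an unadjusted p under 0.05 in limma. Among 16 clock genes 1 fell, the clock output gene Dbp (-0.46, adjusted p = 0.044), and 0 rose, as over the list alone (median -0.12, camera adjusted p = 0.285), and fry called the list lower (adjusted p = 0.02). Among 25 cholesterol synthesis genes 1 fell, the sterol isomerase Ebp (-0.62, adjusted p = 0.0297), and 0 rose, as over the list alone. Their median was 0.04, their mean -0.06 and the test's direction higher (camera adjusted p = 0.88). At an unadjusted p under 0.05, limma gave 1 higher clock and 3 higher cholesterol genes.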
